A study of Rattus norvegicus with 6 samples.

How the data were processed

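MicroRNA abundance was measured in dorsal root ganglia (DRG), which hold the cell bodies of sensory neurons, from 6 male Sprague-Dawley rats on Affymetrix GeneChip miRNA 4.0 arrays, with 1 array per rat. Per the labels' protocols, total RNA was tailed with poly(A) and labelled with biotin, and the lumbar ganglia L3 to L6 of both sides were combined within each rat, so every array is a separate animal and no RNA was pooled across animals.

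The deposited log2 values were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, equalises the arrays' distributions and summarises the probes of each probe set on the log2 scale, so differences between rats that affect most small RNAs alike would largely be removed before deposit. Software versions, options, detection calls and any filter that set the 1277 rows of the table are not given in the sources used here. The quartiles of the 6 columns were close but not identical. A test on these values therefore starts from log2 signals that were already normalized, and no further normalization was applied in the main analysis. Scanner files were not used here, and no read or molecule counts lie behind the values. The precision of a group mean or of a difference between groups is limited by the number of arrays.

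The rows carry numeric probe-set IDs, and neither the table nor the RefSeq gene table used here pairs them with miRNA names (0 of 1277 IDs matched). No miRNA is therefore named, mature and stem-loop probe sets were not told apart, and the 20 miRNA lists that had been fixed before the data were examined were not tested. The planned tests of mature probe sets alone, of the lists and of members within a list were not run for the same reason. At most 2 IDs are printed per direction. All 6 per-sample columns were used.

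Groups came from the disease state in the labels: 3 diabetic and 3 control rats. Each probe set was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend or robust estimation, two-sided, all 6 arrays, no block), with Benjamini-Hochberg adjustment over the 1277 probe sets and a threshold of 0.05. A second count took probe sets at an unadjusted p below 0.05 with a change of at least 1.5-fold. Intervals are 95% confidence intervals from the same fit. Probe sets with a mean of at least 5 over the 6 arrays are called bright and the rest dim. The rule for single probe sets, fixed before the data were examined, took the 10 with the largest log2 difference in each direction, first among those past the adjusted threshold and then among those at an unadjusted p below 0.05. It also took the 3 with the highest mean. Its preference for mature probe sets could not be applied. Array similarity was described by Pearson's r across probe sets and by the first principal component, tested over the 10 ways of dividing 6 arrays into 3 and 3.

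The labels number the rats 1 to 3 in both groups. They state that rats were assigned and chosen at random, so the numbers were not taken as pairs. After group means were removed, same-numbered rats correlated at -0.02, 0.08 and 0.07 over all probe sets and at 0.18, -0.04 and 0.30 over the bright ones. Differently numbered rats gave -0.084 to 0.030 over all probe sets and -0.36 to 0.25 over the bright ones. The highest value was a same-numbered one both times, so these correlations do not exclude pairing.

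The test was tested on simulated data with the real means and spreads of the 1277 probe sets in the diabetic and control rats. With 200 bright probe sets changed, 50 for each fold, limma recovered 53.3% of 1.5-fold, 87.2% of 2-fold, 98.3% of 4-fold and 99.8% of 8-fold changes at an adjusted p below 0.05, and 5.66% of its calls were false. With 10 changed bright probe sets of 1 size, it recovered 0% of 1.5-fold, 34.0% of 2-fold, 88.0% of 4-fold and 97.5% of 8-fold changes. No dim probe set was changed, and noise was drawn independently for each probe set. The percentages therefore do not cover dim probe sets or variation that probe sets share. The changed probe sets were drawn from all 315 bright ones, and 42 of these are among the last 59 IDs, which may not be miRNAs. The observed SD of each probe set was also taken as its true SD, which can make the simulated spreads more uneven than the real ones.

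Alternatives changed 1 choice at a time: the rat number as a block, repeated quantile normalization, centring of each array on the median of its brighter probe sets (those whose mean was at or above the table median), 2 filters on dim probe sets, trended and robust moderation, no moderation, array weights, other thresholds, and leaving out each array. Keeping identical rows once, leaving out the last run of IDs and leaving out both arrays numbered 3 were added after seeing the data. Figures were drawn with matplotlib 3.10.9.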

Results

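The study asked which miRNAs differ in abundance between the DRG of rats made diabetic with streptozotocin (STZ), a toxin of the insulin-producing beta cells of the pancreas, and the DRG of normal rats. The diabetic group received 1 intraperitoneal dose of 65 mg/kg and the control group the citrate vehicle. Diabetic rats were retained at a blood glucose of 16.7 mM or above, and ganglia were taken 8 weeks after the injection. There were 3 diabetic and 3 control rats, each on its own array, with values for 1277 probe sets. Signals were log2 RMA values, and the medians of the 6 arrays lay between 0.91 and 1.01 with upper quartiles between 4.80 and 5.08. In the table as a whole, 315 probe sets (24.7%) were bright, with a mean of at least 5, and 658 (51.5%) had a mean below 1.

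No probe set was called higher or lower in the DRG of diabetic rats. None passed an adjusted p of 0.05 in limma's test with Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.138. At an unadjusted p below 0.05 there were 106 probe sets (8.30%), 61 higher and 45 lower in diabetic rats, where chance alone gives about 63.9. Of these, 42 differed by at least 1.5-fold, 23 higher and 19 lower. With each array centred on the median of its brighter probe sets, this split became 14 higher and 33 lower. Centring also moved the median difference over all probe sets from -0.00109 to -0.078, which favours lower values. With repeated quantile normalization the split was 21 higher and 20 lower. In the main test, a difference of at least 2-fold was seen in 14 of the 106, of which 4 were higher and 10 lower. Leaving out control rat 2 raised the 42 to 83, raised the count past the adjusted threshold from 0 to 1 and raised the 106 to 151. Leaving out any other single array lowered the 106 to between 75 and 90, and leaving out both arrays numbered 3 gave 72, with about 63.9 from chance each time. Fewer arrays alone can lower such counts, and no other pair of arrays was left out for comparison.

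**Figure D1:**
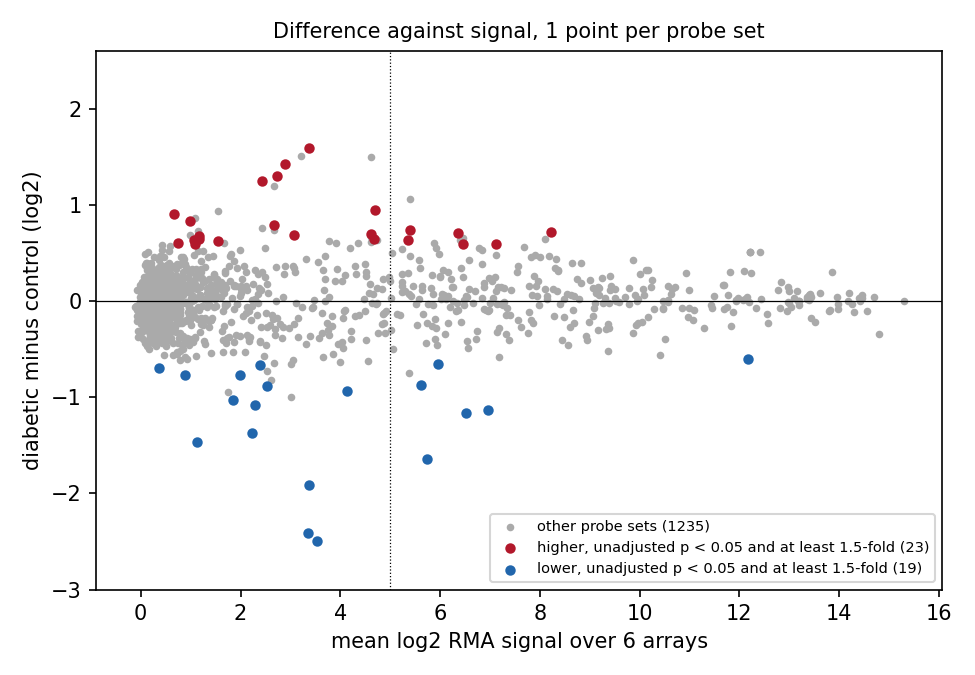
Difference between diabetic and control rats (log2, y axis) against the mean log2 RMA signal over 6 arrays (x axis), with 1 point per probe set and a dotted line at a mean of 5. The 23 red and 19 blue points are probe sets at an unadjusted p below 0.05 with at least 1.5-fold higher or lower signal in diabetic rats, and most of them lie left of the dotted line.

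Among the 315 bright probe sets, the median SE of a difference was 0.16 on the log2 scale and the median absolute difference was 0.14. The 95% confidence interval of 277 of them (87.9%) lay wholly within 2-fold in either direction, and that of 168 (53.3%) lay within 1.5-fold. These 315 include 42 of the 59 IDs in the last run of the table, several of which repeat the same signal levels and which may not be miRNAs. Without them, a choice made after seeing the data, the median absolute difference of the other 273 was 0.16, and the intervals of 235 (86.1%) lay within 2-fold and of 127 (46.5%) within 1.5-fold. At an unadjusted p below 0.05 there were 35 bright probe sets, against 15.8 from chance. None of the 35 was in the last run, and 12 of the 35 differed by at least 1.5-fold, 6 in each direction. The only bright probe sets among the 14 that differed by at least 2-fold were 3 that were lower in diabetic rats. Among the 962 dim probe sets, 71 were at an unadjusted p below 0.05 against 48.1 from chance, and 30 of them differed by at least 1.5-fold, 17 higher and 13 lower. Without background or detection values, it is not known which dim signals lie above background, so the background may set part of the size and rank of any difference of a dim probe set, in either direction.

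The largest lower value in the deposited signals of diabetic rats belonged to probe set 20524594, which is dim. Its signal was 2.29 ± 0.51 (SD, n = 3) in diabetic and 4.79 ± 0.90 (SD, n = 3) in control rats. The difference of -2.50 (SE 0.47) had an adjusted p of 0.395 in limma. Probe set 20504155 followed, with 2.15 ± 0.69 (SD, n = 3) against 4.56 ± 0.92 (SD, n = 3), a difference of -2.41 (SE 0.52) and an adjusted p of 0.395 in limma. Both were lower in each diabetic rat than in any control rat, which their choice by size and p favours. Both are dim by their mean over all arrays, so neither their rank nor the size of the difference is known to lie free of background.

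The smallest p in the table belonged to the bright probe set with the fourth-largest lower value. Its signal was 4.92 ± 0.064 (SD, n = 3) in diabetic and 6.56 ± 0.39 (SD, n = 3) in control rats, a difference of -1.64 (SE 0.21) or 3.12-fold. Its p was 0.000108 unadjusted and 0.138 adjusted in limma. A second bright probe set differed by -1.13 (SE 0.17), or 2.20-fold, with 6.39 ± 0.26 (SD, n = 3) in diabetic against 7.52 ± 0.13 (SD, n = 3) in control rats and an adjusted p of 0.199 in limma. These 2 were the probe sets that passed the adjusted threshold when only those with means of at least 5 were tested (adjusted p of 0.0392 and 0.0398 in limma) and when arrays were centred on their brighter probe sets (0.00992 and 0.0437). The probe set with the smallest p also passed with repeated quantile normalization (0.0176), array weights (0.0286) and control rat 2 left out (0.0135). The second did not pass there (0.154, 0.129 and 0.214). Neither passed when only probe sets at or above the table median were tested (0.139 and 0.162) or without moderation of the variances (0.594 for both). Neither passed with the replicate block (0.134 for both) or with any other single array left out (0.234 to 0.618). The third bright probe set with a lower value of at least 2-fold differed by -1.17 (SE 0.35) with an adjusted p of 0.583 in limma. The other 5 of the 10 lower probe sets were dim, with differences from -1.91 to -1.03. Among these, the -1.91 became -0.95 and the -1.37 became -0.79 without diabetic rat 3, and the -1.08 became -0.72 without control rat 1.

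In the other direction, the 2 largest values among probe sets at an unadjusted p below 0.05 again belonged to dim probe sets, under the same background limit. Probe set 20506496 had a signal of 4.17 ± 0.41 (SD, n = 3) in diabetic and 2.59 ± 0.57 (SD, n = 3) in control rats. The difference of 1.59 (SE 0.33) had an adjusted p of 0.395 in limma. Probe set 20502448 had 3.61 ± 0.43 (SD, n = 3) against 2.19 ± 0.42 (SD, n = 3), a difference of 1.42 (SE 0.29), also with an adjusted p of 0.395 in limma. The remaining 8 of the 10 higher probe sets differed by 0.72 to 1.30. Among these, 1 of 0.79 became 0.48 without control rat 2 and 1 of 0.74 became 0.44 without control rat 3. The tenth was the brightest of the 10, at 8.59 ± 0.25 (SD, n = 3) in diabetic against 7.87 ± 0.14 (SD, n = 3) in control rats, with an adjusted p of 0.472 in limma. In all, the 3 rats of one group lay wholly above or below the 3 of the other for 175 probe sets (13.7%), where chance gives 10%.

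**Figure D2:**
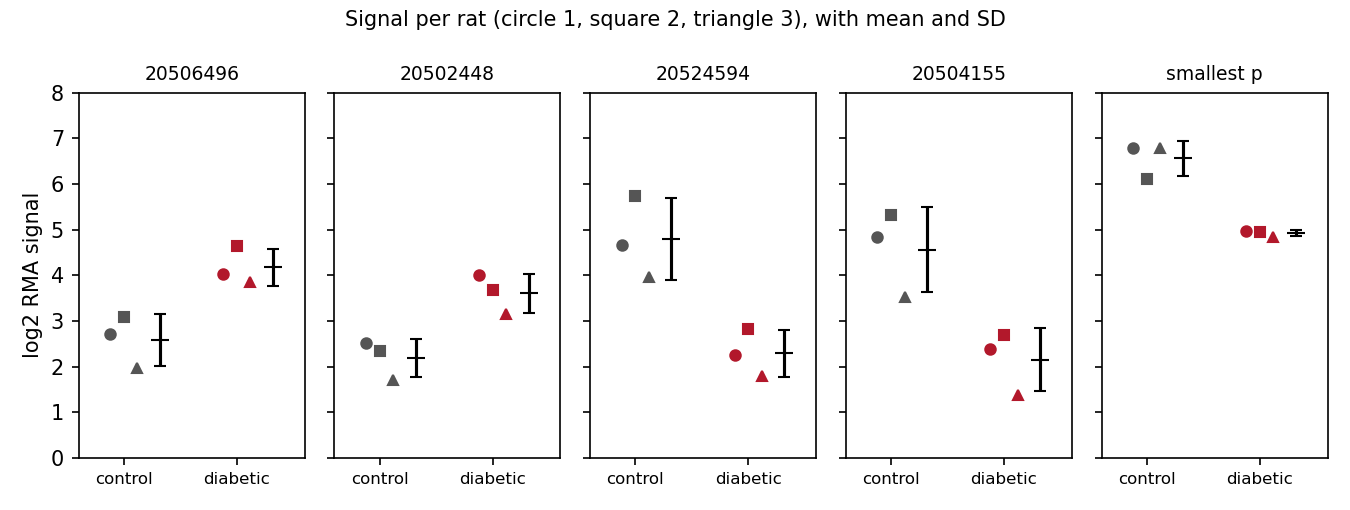
Log2 RMA signal (y axis) of each rat in the control and diabetic groups. Among probe sets at an unadjusted p below 0.05, the 2 with the largest higher and the 2 with the largest lower values in diabetic rats are shown. The last panel is the probe set with the smallest p. Points are single rats, and the bar beside them is the mean with the SD of 3 rats. In all 5 panels the groups do not overlap, which the choice of these probe sets from the same data by size or p favours. The tightest group is that of the diabetic rats in the last panel (SD 0.064).

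The 3 probe sets with the highest mean all belong to the last run of IDs, and the first of them was at the array maximum on each array, so its difference is fixed near 0. The others differed by -0.35 and 0.041 on the log2 scale, with adjusted p of 0.603 and 0.931 in limma, and whether any of the 3 measures a DRG miRNA is not known. Outside that run, the 3 with the highest mean, chosen after seeing the data, differed by -0.099 (SE 0.12), -0.12 (SE 0.13) and -0.031 (SE 0.12) on the log2 scale, with adjusted p of 0.829, 0.816 and 0.943 in limma.

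By Pearson's r, whole profiles were nearly as similar between groups as within them. Signals differed far more between probe sets than between arrays, which keeps r high for any 2 arrays. A high r therefore does not show that the groups are alike. Pearson's r across probe sets, which are not independent replicates, averaged 0.993 within the control group, 0.993 within the diabetic group and 0.992 between groups, with a range from 0.989 to 0.995. The within-group mean exceeded the between-group mean by 0.00118, and no other division of the 6 arrays gave a larger excess (exact permutation test over 10 divisions, one-sided p = 0.1, the smallest that the design allows). This excess was 0.000657 without control rat 3 and 0.00185 without control rat 2. The first principal component held 31.1% of the variance. It placed diabetic rats at 0.13, 0.15 and 0.71 and control rats at -0.35, -0.07 and -0.58, so the groups did not overlap. The difference of their means gave the smallest p possible (exact permutation test, two-sided p = 0.1). Groups that do not overlap always give this p, so it adds nothing to the scores.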

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

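No probe set passed the adjusted threshold of 0.05 in limma, with 106 at an unadjusted p below 0.05. The count became 2 with the replicate block, 1 with repeated quantile normalization, 2 with arrays centred on their brighter probe sets, 2 with means of at least 5 and 1 with array weights, all lower in diabetic rats. With means of at least 5 fewer probe sets (315) were tested; for the others the cause was not tested. It stayed at 0 under the other alternatives run, except that leaving out 1 array gave 0 to 1, the 1 coming without control rat 2. The count of 42 at an unadjusted p below 0.05 and at least 1.5-fold became 12 with means of at least 5, 22 with no moderation, 14 at 2-fold and 106 with no fold threshold; apart from the 22, whose cause was not tested, these follow from the filter or threshold. Leaving out 1 array gave 38 to 83, highest without control rat 2, where 30 of the 83 were among the 42. Without both arrays numbered 3, chosen after seeing the data, 24 of 47 were. The rat numbers were not shown to pair the animals, so the 2 calls of the replicate block, the 2 printed IDs with lower values, are not a paired result. For the 20 probe sets chosen by size, 124 of 324 alternative values leave the difference as it is, and the choice by size favours a stable direction, so direction is not read as a test; 9 passed the adjusted threshold, in 4 probe sets. The adjusted p of the probe set with the smallest p ranged from 0.00992 with centring to 0.618 without control rat 1, that of the second bright probe set from 0.0398 with means of at least 5 to 0.618 without control rat 1, and that of the 4 printed IDs from 0.0426 to 0.740. The excess of within-group over between-group r (0.00118) was 0.000657 to 0.00185 with 1 array left out and 0.00213 in the 639 brighter probe sets, the only alternatives run for it. The alternatives for mature probe sets alone and for the lists were not run for lack of names. With 3 arrays a group, 34.0% of simulated 2-fold changes were recovered when 10 bright probe sets changed.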

Other observations

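The tests of other splits, of the last run of IDs and of neighbouring IDs in this part were chosen after the results they bear on had been seen. Rat 3 of the diabetic group and rat 3 of the control group lay at opposite ends of the first principal component, at 0.71 and -0.58.

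More probe sets were at an unadjusted p below 0.05 than chance gives (106 against 63.9). Leaving out both arrays numbered 3 gave 72, and leaving out 1 array gave 75 to 151. The 151 came without control rat 2 alone, with at most 90 otherwise. Fewer arrays alone can lower such counts, so they do not show which arrays the excess rests on. Dividing the 6 arrays differently gave at most 85 in the other 9 splits, and 1 of the 10 splits, the real one, reached 106; at 1.5-fold or more the real count was 42 and the highest other 39, again 1 of 10, and past the adjusted threshold all 10 splits gave 0. With 10 splits no share can fall below 0.05. The other 9 splits also put rats of both groups on each side. A difference between the groups would widen the spread within sides and lower those counts, so they are not a clean measure of chance. Rows with identical values (11 rows in 5 sets) hold 6 repeated copies, and with each set kept once the real split gave 104. Whether array scaling accounts for part of the real split's lead is not settled. With arrays centred on their brighter probe sets the real split gave 94. The highest other split, which grouped diabetic rats 1 and 2 with control rat 1, gave 130, a ratio of 0.723. That other split gave 46 before centring, so the ratio comes mostly from its rise and not from the fall of the real count. Repeated quantile normalization left the real count at 107, and the other splits were not counted under it. No test here separated a biological effect of diabetes from array scaling as the source of the excess, so both stay open.

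The last 59 IDs of the table form a run of their own, with 42 of them at a mean of at least 9, against 142 in the whole table. Its first 21 IDs repeat 1 series of 7 signal levels 3 times, with r of at least 0.999 between repeats and gaps of at most 0.089, which is a pattern that control material added in steps could give, although the table does not say what these IDs are. All 21 were higher on the array of rat 3 than on the mean of the other 2 arrays of its group, in both groups, by a median of 0.25 in diabetic and 0.21 in control rats. Array scaling stays open as the cause, because the excess over 65 other probe sets of the same brightness was 0.32 in the diabetic group (95% bootstrap interval 0.25 to 0.38) but 0.064 in the control group (-0.025 to 0.30). Less sample RNA on both of these arrays also stays open: the 65 other probe sets shifted by -0.072 on the diabetic array (-0.13 to -0.018) but by 0.142 on the control array (-0.093 to 0.19). These bootstrap intervals came from resampling probe sets, not rats or arrays, so they do not measure variation between rats. The 21 IDs were resampled as separate members although they repeat 7 levels, so the intervals of the excess may be too narrow. No biological explanation was tested.

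Neighbouring IDs might mark related small RNAs, such as products of 1 precursor, and so shift together. Among 117 pairs of consecutive bright IDs outside the last run, the differences between diabetic and control rats correlated across pairs at r = 0.20 and rho = 0.20 (permutation test, one-sided p = 0.0142 from 100000 shuffles), and 67 pairs (57.3%) had the same sign; r was 0.18 without the 2 pairs that shifted most. Pairs are not independent replicates. Other splits of the same arrays gave up to 0.35, which is 0.147 above the real split (-0.147 as real minus highest other). The correlation is thus consistent with variation that neighbouring IDs share within groups, and it does not separate a response to diabetes from that variation.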
